A study of Arabidopsis thaliana with 6 samples.

How the data were processed

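Chromatin immunoprecipitation with an anti-Myc antibody and single-end sequencing of 50 cycles were done on dark-grown seedlings of a PIF4-Myc line and of the wild type, with 3 libraries per group and 6 libraries on 1 lane, per the labels' protocols. Fragments of 200 to 300 bp were selected. The data analysed here are the 3 peak lists of the PIF4-Myc replicates; the wild-type libraries entered only as the control inside each list. The submitters' processing notes name CASAVA 1.8.0, Bowtie 0.12.7, MACS 1.4.1 and the build TAIR10. Peaks were called per PIF4-Myc library, not on pooled libraries, per the file headers, with MACS 1.4.0rc2 for lists 1 and 3 and MACS 1.4.1 for list 2, at a p cutoff of 1e-05 and a band width of 300. The headers name 1 control for lists 1 and 2 and another for list 3, while the labels give each group 3 libraries.

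Tags per peak were deposited by the authors as read counts within each peak. In list 1 the deposited tag values were treated as a score, since all were multiples of 5. The peak score is −10 times log10 of the p-value as the authors' peak caller wrote it, and reached 3100 at most. Fold enrichment is the authors' ratio of the tags at the summit to the local expectation. The false discovery rate is a percent given by the authors' peak caller. Starts, ends, lengths and summits are positions in bp as deposited. Folds and scores were used to describe, rank or filter peaks within a list, to choose the summit of a merged region and to choose which genes to name, and folds also to correlate lists by rank.

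Depth is known only from the headers. Treatment tags numbered 12766185, 9385807 and 12292381 for lists 1, 2 and 3. The tags after filtering were given as 112342435, which exceeds the total, for list 1, 8634942 for list 2 and 10730507 for list 3. The total of the control of list 1 was unreadable, and the controls of lists 2 and 3 had 10278504 and 11154405 tags. No depth was available per position, so peak folds carry no counting interval. The exact intervals on shares of genes cover counting error only.

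Peaks on chromosomes 1 to 5 were merged where they overlapped by at least 1 bp, and a region was shared when at least 2 lists had a peak in it. The summit of the peak with the highest fold stood for the region. Sharing was compared with 1000 random placements of all peaks within their chromosomes, keeping widths, with a one-sided permutation p, and, as a choice made after seeing the data, with placements within 50 kb of each peak. The share of summits outside protein-coding genes was compared with 1000 sets of random positions. Fold correlations used Spearman's coefficient with 10000 permutations, two-sided, over regions with both lists.

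Genes came from the RefSeq annotation of assembly TAIR10.1, while the peaks are on TAIR10. The nuclear chromosomes were taken to have the same coordinates in both, and this was checked by shifting the summits: 64.0% lay outside genes without a shift, 61.1% and 61.8% after 250 bp to either side, and 43.5% and 44.0% after 2000 bp. No annotation coordinates are given, only peak positions. The annotation used carries no strand, exon or sequence. The planned share of upstream summits was therefore replaced by the share outside genes, and genes were assigned when a summit lay in the gene or within 2 kb of either end. G-box, PBE-box and other 6-base motif shares and the exon check at PIF4 and PIF1 were not analysed here.

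The 21 gene lists, of which 3 were controls, and the rule for named genes were fixed before the data were examined. All 120 genes given by identifier were found in the annotation. Family members were matched by symbol, and 16 genes that only shared a symbol with a family were taken out after the matches had been read, without regard to their peaks. The list of ribosomal proteins holds cytosolic and organellar ones. Of 483 distinct genes, 15 are on more than 1 list. Each list was tested against all 27444 protein-coding genes with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment at 0.05. Named genes are PIF4, PIF1 and all shade and PIF targets. From every other list, up to 4 members with a region in most lists and then the highest median fold were named. The last 10 names are genes outside the lists with a region in all 3 peak lists and the highest median fold.

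Alternatives were the authors' false discovery rate of 1%, the better-ranked 50% of each list by p, equal numbers of peaks, a reciprocal overlap of 50%, summits within 100 bp, each list left out in turn, gene windows of 1 and 5 kb, the nearest gene alone, and a background matched on gene length in 10 bins. Regions that needed a list 1 peak, regions of lists 2 and 3 without one, and regions shifted together along each chromosome were added after seeing the data. On simulated lists of 19201 peaks with 300 regions planted in all 3 lists, 293 were found above the random mean, and 2 of 20 simulations without planted regions had p under 0.05. The planted peaks were centred on one another, so their overlap was set by design and checks only the counting. Of 10 simulated lists of 30 genes with regions at 50% of their members, 10 passed the threshold, as did 1 of 40 random lists. Each of the 10 had exactly that share, so they could only pass or fail together and give no rate of detection. Lists of other sizes were not simulated. The gene list simulations drew genes singly at random. They therefore do not give the rate of false calls for neighbouring genes that share a summit. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.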

Results

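Binding of the bHLH transcription factor PIF4, which promotes elongation growth and is removed after phytochrome activation by light, was mapped by chromatin immunoprecipitation and sequencing in whole Arabidopsis thaliana seedlings. The seedlings had grown for 3 days in darkness at 21 °C after 3 h of white light to start germination. A line overexpressing Myc-tagged PIF4 was compared with the wild type, both precipitated with an anti-Myc antibody. Each group had 3 libraries, and per the labels each library pooled DNA from 4 ChIP assays of 2 biological replicates. The deposited data were 3 peak lists, numbered here by the PIF4-Myc replicate, each called by the authors against a wild-type ChIP. The list headers gave 12766185, 9385807 and 12292381 treatment tags for replicates 1, 2 and 3. All fold enrichments below are the authors' values for single peaks and carry no replicate error. Each fold is the highest of its list within a merged region, whose peaks can lie apart. For a gene with several regions, the folds given are those of the region in most lists and then of the highest median fold. Other peaks near such a gene can have a higher fold.

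The lists differed widely in size and strength. List 1 held 12177 peaks with a median width of 339 bp and a median fold of 0.99, and 51.2% of its peaks had a fold below 1. List 2 held 4093 peaks with a median width of 811 bp and a median fold of 2.46. List 3 held 2931 peaks with a median width of 850 bp and a median fold of 4.17. The mean was 6400 ± 5036 peaks (SD, n = 3 lists), and 3512 without list 1. The authors' false discovery rate had a median of 3.81% in list 1, 63.9% in list 2 and 65.2% in list 3, and 166, 85 and 2 peaks stood at 1% or less. Peaks named below differ widely in this rate, for example 0% at PIF6, 76.4% at EIN3 and 84.3% at IAA4 in list 3. Every tag count in list 1 was a multiple of 5, against 20.5% of the counts in list 2 and 20.8% in list 3, and the p-values and folds of list 1 describe that list alone.

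The PIF4 gene itself (AT2G43010) carried a peak with its summit inside the gene in all 3 lists. On chromosome 2 of TAIR10 the peak spanned 17887109 to 17887884 in list 1, 17886919 to 17889972 in list 2 and 17886919 to 17889108 in list 3, with folds of 2.18, 5.64 and 5.05. By p-value it ranked 14 among 7677 in-gene peaks of list 1, 2 among 1579 in list 2 and 9 among 1038 in list 3. PIF1 (AT2G20180), a close relative that represses seed germination, had an in-gene peak in list 1 only, with a fold of 1.18. It was looked at because the design text names the tagged line P1M, and the files do not settle what that name stands for. The files do not separate DNA of the transgene from binding at the native PIF4 gene, and exon positions were not used here.

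Shared binding was asked of the lists as the labels present them, as replicates. Merging overlapping peaks gave 3153 regions with a peak in at least 2 lists, against 1013 ± 27.9 (SD over 1000 random placements), a ratio of 3.11 (one-sided permutation p = 0.001, the smallest the placements can give). All 3 lists had a peak in 785 regions, against 40.1 ± 6.43 by random placement (permutation p = 0.001). Of the shared regions, 1626 came from lists 2 and 3, 655 from lists 1 and 2, and 87 from lists 1 and 3, besides the 785. Without list 1, 2 or 3 the others shared 2412, 852 and 1434 regions. Regions with peaks of both lists 2 and 3 numbered 2411, 12.6 times the random mean, while the ratio was 2.79 for lists 1 and 2 and 2.26 for lists 1 and 3. With each peak placed at random within 50 kb of its own position, a comparison chosen after seeing the data, the ratio was 2.64 for at least 2 lists, 10.3 for all 3 lists, 8.43 for lists 2 and 3, 2.38 for lists 1 and 2 and 1.90 for lists 1 and 3 (permutation p = 0.001 for each). With peaks at the authors' false discovery rate of 1% or less, 11 regions were shared and 0 were in all 3 lists. List 3 had only 2 peaks at that rate, so at most 2 regions could have been in all 3 lists. The 11 regions therefore come mainly from lists 1 and 2. The headers named the same control for lists 1 and 2, so part of their overlap may come from that control.

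Fold enrichment followed the same split between the lists. Across the 2411 regions of lists 2 and 3 the folds had a Spearman correlation of 0.906 (permutation p = 0.0001, the smallest possible with 10000 permutations). Across the 1440 regions of lists 1 and 2 it was 0.0836 (permutation p = 0.0014), and across the 872 regions of lists 1 and 3 it was 0.134 (permutation p = 0.0001). Both low correlations missed the threshold in the better-ranked 50% of each list. The correlations are across regions, which are not independent replicates. Lists 2 and 3 also shared exact peak edges. Of their 2454 overlapping peak pairs, 1240 began at the same base, and at most 15 pairs lay at any other distance within 20 bp. Lists 1 and 2 began at the same base in 53 of 1617 pairs, against at most 6 at any other distance within 20 bp, and lists 1 and 3 in 0 of 971. Neither lists 2 and 3 nor lists 1 and 2 were therefore read as independent replicates. Values without list 2, which rest on lists 1 and 3 alone, are given beside the main ones where they change a call, as are values resting on a list 1 peak.

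**Figure D1:**
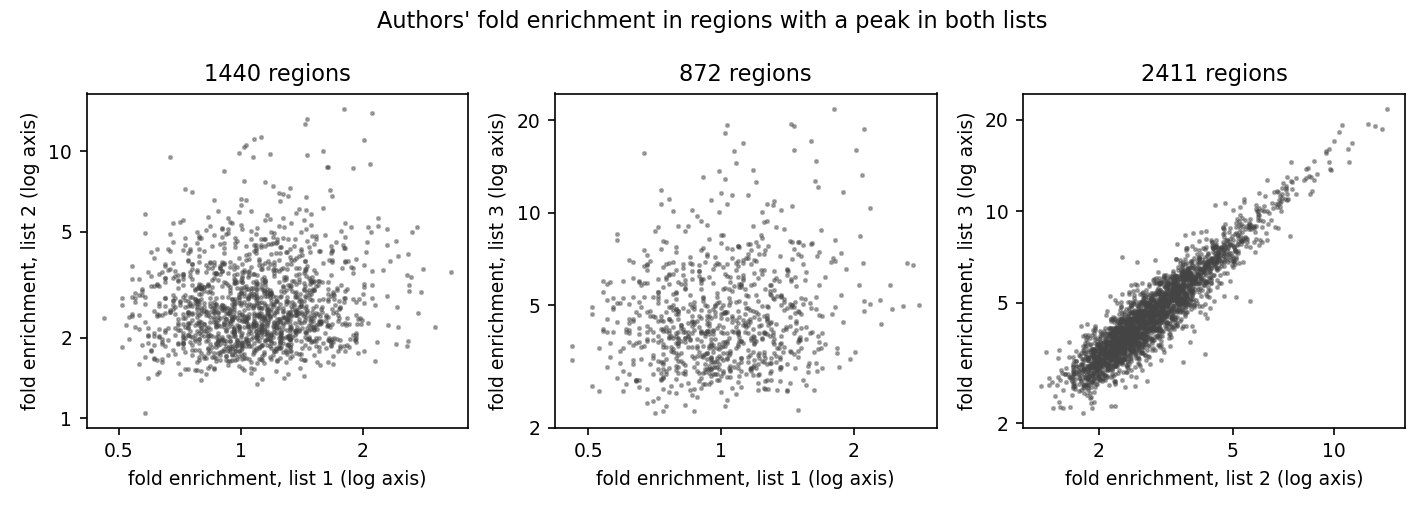
Authors' fold enrichment (log axes, no unit) of every region with a peak in both lists of a pair; each point is 1 region, at the highest fold of each list in it. The 2411 regions of lists 2 and 3 lie along a narrow band, and the 1440 and 872 regions that involve list 1 form broad clouds.

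**Figure D2:**
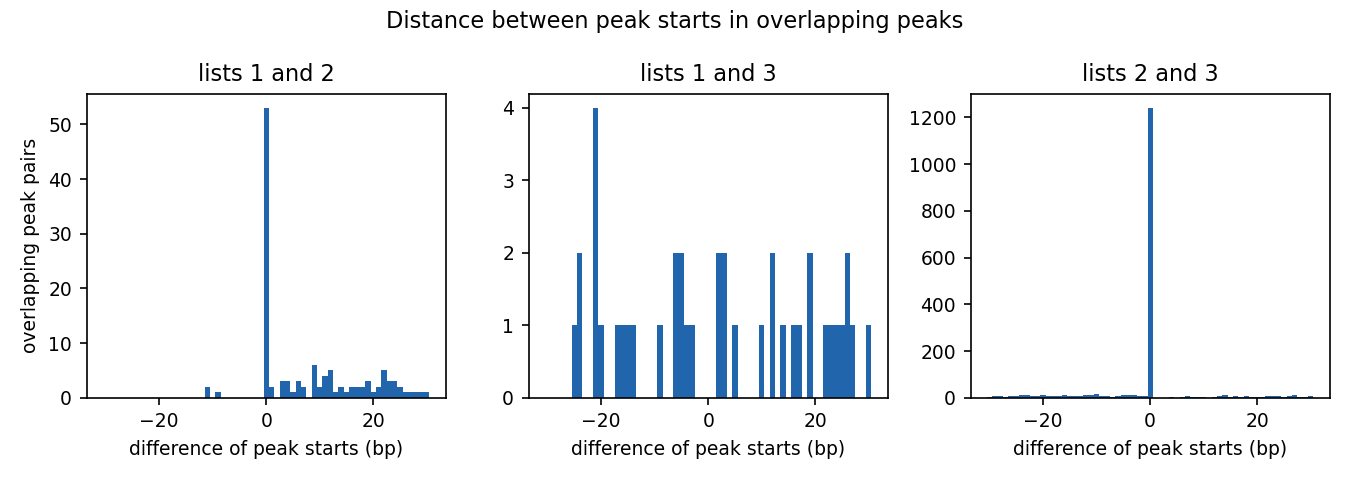
Number of overlapping peak pairs (vertical axes, own scale per panel) by the difference between their start positions in bp, for each pair of lists. The bar at 0 bp holds 1240 pairs for lists 2 and 3, 53 for lists 1 and 2 and 0 for lists 1 and 3.

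Shared regions lay mostly between genes. Of the 3153 summits, 64.0% fell outside every protein-coding gene, against 45.8% ± 0.879 (SD) for random positions (one-sided permutation p = 0.001, the smallest possible). The share was 61.4% for all peaks of list 2, 64.6% for list 3 and 66.2% for the 785 regions in all 3 lists. A region's summit is that of its highest-fold peak, and folds ran highest in list 3. At the named genes with a region in all 3 lists, it came from list 3 except at PIF4. The 66.2% is therefore not separate from the share of list 3 and does not show that the 3 lists agree. List 1 went the other way, with 37.0% of its summits outside genes against 45.8% at random (permutation p = 0.001 for a lower share). Of the shared summits, 88.6% lay in a gene or within 2 kb of one. Only 2.09% lay in the gene-poorest 10% of 500 kb bins. The shared regions reached 4180 of 27444 protein-coding genes (15.2%), counting genes that held a summit or had one within 2 kb of either end. The count was 1319 without list 2, 2113 without list 3 and 3208 without list 1.

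Known targets of shade and PIF signalling often held a shared region. A shared region lay at 15 of the 20 genes (75%, exact 95% interval 50.9 to 91.3), against 15.2% of all genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 8.15e-08 over 21 lists). PIL1 (AT2G46970), a bHLH gene that is induced rapidly by shade, had a region at 19296733 to 19299808 on chromosome 2, with folds of 1.46, 13.3 and 19.2 in lists 1, 2 and 3. CKX5 (AT1G75450), a cytokinin oxidase, had one at 28318226 to 28319370 on chromosome 1, with folds of 2.11, 13.9 and 18.7. ST2A (AT5G07010), a sulfotransferase that acts on a jasmonate derivative, had folds of 1.44, 12.7 and 19.5 at 2176990 to 2178692 on chromosome 5. HFR1 (AT1G02340), a bHLH repressor of shade responses, had folds of 1.2, 7.45 and 12.6 at 464664 to 470085 on chromosome 1. Its list 1 fold of 1.2 came from a peak at 465999 to 466325 with its summit in the gene. The list 1 peak nearest the region's summit, at 468988 to 469535, had a fold of 0.72. The summits that stood for these 4 regions were outside the genes and within 2 kb. The PIL1 summit lay 1214 bp from PIL1 and only 420 bp from the neighbouring gene ASY3. Over the whole list, the listed gene was the nearest one for 18 of 24 regions (75%).

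PAR1, FHL, IAA19 and ATHB4 also had a region in all 3 lists, with list 2 folds of 4.78, 4.93, 3.66 and 6.10 and list 3 folds of 8.03, 8.13, 6.77 and 8.85. Their list 1 folds were only 1.2, 0.58, 0.89 and 1.39, below 1 at FHL and IAA19. YUC8, XTH15, ACS8, HAT1, PAR2 and ATHB2 had regions in lists 2 and 3 alone, from folds of 8.39 and 13.9 at YUC8 to 2.34 and 4.04 inside ATHB2. BR6OX2 had one in lists 1 and 2, with folds of 1.81 and 1.79. No shared region was assigned to IAA29, PSY, PORC, CHLH or FT. At IAA29, peaks at 15580444 to 15581617 on chromosome 4 in list 2 and 15580444 to 15581755 in list 3, with folds of 5.48 and 7.68, had their summit just beyond the 2 kb limit. The list stayed past the threshold with regions that needed a list 1 peak and also a peak of list 2 or 3, at 9 of 20 genes (adjusted p = 0.000279, Fisher's exact test), and without list 2, at 8 of 20 (adjusted p = 4.39e-05). List 1 alone did not pass the threshold: its peaks reached 12 of the 20 genes (60%) and 53.2% of all genes (Fisher's exact adjusted p = 0.847). Its 2931 best-ranked peaks reached 8 of the 20 (40%), against 14.6% of all genes, an odds ratio of 3.90. There the Fisher's exact p was 0.00504 unadjusted and 0.106 adjusted. Of the 21 gene lists, 0 passed in list 1 alone either way, with 0 and 4 at an unadjusted Fisher's exact p under 0.05.

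**Figure D3:**
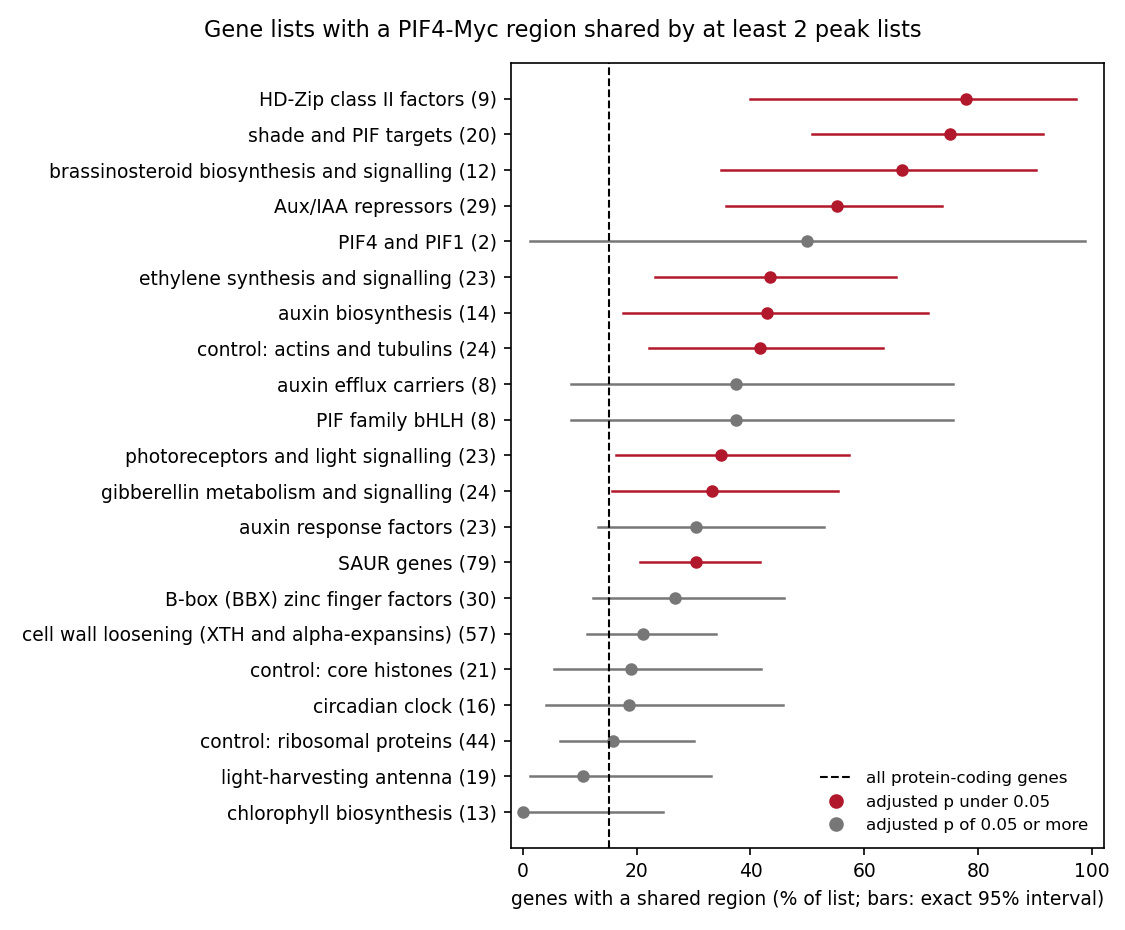
Share of the genes of each list (percent, horizontal axis) with a region shared by at least 2 peak lists; bars are exact 95% binomial intervals, numbers in parentheses count the genes, and the dashed line marks the 15.2% of all protein-coding genes. Red marks the 10 lists with an adjusted p under 0.05, which include actins and tubulins, a control list; without list 2 and without list 3 the number was 3 each.

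Genes of HD-Zip class II, homeodomain factors of which several respond to shade, held a region at 7 of 9 members (77.8%, exact interval 39.99 to 97.2, Fisher's exact adjusted p = 0.000359). ATHB2, HAT1 and ATHB4 among them are also on the list of shade and PIF targets. HAT2 had folds of 1.03, 4.10 and 6.79 over lists 1 to 3, HAT22 had 0.94, 2.54 and 4.61 in one region and 6.00 and 10.25 in another of lists 2 and 3 alone, and HAT1 had 4.02 and 6.02 in lists 2 and 3. Photoreceptor and light signalling genes had a region at 8 of 23 (34.8%, interval 16.4 to 57.3, Fisher's exact adjusted p = 0.0386). HFR1 and FHL among these are also on the shade list, so neither call is wholly separate from that of the shade targets. PHYB (AT2G18790), the main red light photoreceptor of light-grown plants, had a region at 8137816 to 8142077 on chromosome 2, outside the gene, with folds of 0.99, 9.83 and 13.7. The region of PHYA, the photoreceptor that accumulates in darkness, had its summit in the gene, with folds of 0.76, 3.78 and 5.86. The HD-Zip list had 3 members and a Fisher's exact adjusted p of 0.0942 without list 3, and 2 members and 0.38 with summits within 1 kb of the gene. Photoreceptors had an adjusted permutation p of 0.126 against genes of matched length, and Fisher's exact adjusted p-values of 0.0502 with regions that needed a list 1 peak and 0.17 with a window of 5 kb. They also missed it with regions of lists 2 and 3 without a list 1 peak (Fisher's exact adjusted p = 0.176) and with regions shifted together along the chromosomes (adjusted permutation p = 0.134).

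Auxin genes were reached at several levels. Aux/IAA repressors, short-lived proteins that hold back auxin response, had a region at 16 of 29 genes (55.2%, interval 35.7 to 73.6, Fisher's exact adjusted p = 7.92e-06). IAA2 had folds of 6.15 and 9.29 in lists 2 and 3, IAA7 had 2.76 and 3.65 beside a list 3 peak of 5.67, and IAA4 had 2.36 and 2.95. SAUR genes, small auxin-induced genes tied to cell expansion, had a region at 24 of 79 (30.4%, interval 20.5 to 41.8, Fisher's exact adjusted p = 0.0031). The SAUR gene was the nearest one for 17 of 29 such regions (58.6%), and the test counts genes separately where they share a summit. The SAUR list kept its call with the nearest gene alone and with regions shifted together along the chromosomes. Among SAUR genes with a region in all 3 lists, SAUR9, SAUR50, SAUR72 and SAUR69 came first by median fold, with list 3 folds of 7.98, 6.82, 6.18 and 4.92. Auxin biosynthesis had 6 of 14 (42.9%, interval 17.7 to 71.1, Fisher's exact adjusted p = 0.0325), among them YUC8, YUC9, YUC5 and TAR2, with list 2 folds of 8.39, 5.78, 3.54 and 3.24. Auxin response factors had 7 of 23 and the PIN efflux carriers 3 of 8, with Fisher's exact adjusted p-values of 0.137 and 0.176. The response factors passed with equal numbers of peaks (Fisher's exact adjusted p = 0.0251) and with the nearest gene alone (0.0361). ARF8 had folds of 2.64, 5.01 and 6.87 in lists 1 to 3, and PIN3 had 3.78 and 6.16 in lists 2 and 3.

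The auxin calls rested on lists 2 and 3 together. Without list 2, Aux/IAA, SAUR and auxin biosynthesis genes had 3, 7 and 1 members with a region and Fisher's exact adjusted p-values of 0.28, 0.201 and 0.654. Without list 3 these p-values were 0.179, 0.232 and 0.441, and with regions that needed a list 1 peak they were 0.226, 0.226 and 0.489. The odds ratios were 6.87, 2.44 and 4.18 with all lists and 2.29, 1.93 and 1.52 without list 2.

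Other hormone pathways were also reached. Brassinosteroid genes had a region at 8 of 12 (66.7%, interval 34.9 to 90.1, Fisher's exact adjusted p = 0.000419). BIN2, the kinase that restrains brassinosteroid signalling, had a summit in the gene with folds of 0.97, 2.70 and 5.00, and the biosynthetic gene DWF4 had 3.45 and 6.42 in lists 2 and 3. BAS1 and BIM1 had list 3 folds of 5.65 and 3.62. Ethylene genes had a region at 10 of 23 (43.5%, interval 23.2 to 65.5, Fisher's exact adjusted p = 0.00393). EIL1 and EIN3, the transcription factors at the end of the ethylene pathway, had folds of 7.74 and 2.39 in list 2 and 12.9 and 3.81 in list 3. EIN3 also had a list 3 peak of 3.86. ACO5 and EBF2 had list 3 folds of 3.84 and 2.26, and ACO5 another peak of 6.13. Gibberellin genes had a region at 8 of 24 (33.3%, interval 15.6 to 55.3, Fisher's exact adjusted p = 0.0454). The biosynthetic GA20OX3, the receptor gene GID1B and the catabolic GA2OX4 had list 3 folds of 6.85, 6.92 and 5.90, and the DELLA repressor gene GAI had 3.78, beside a list 3 peak of 8.08 with its summit 932 bp outside the gene. Without list 2 the Fisher's exact adjusted p was 0.0785 for each of these 3 pathways, without list 3 it was 0.0551, 0.0466 and 0.228, and with regions that needed a list 1 peak it was 0.0572, 0.0502 and 0.241. The odds ratios without list 2 were 6.61, 4.18 and 3.97, against 11.2, 4.29 and 2.79 with all lists. Those without list 2 rest on fewer genes with a region and were given no interval, so why these calls were lost was not tested. The control list of actins and tubulins had the same Fisher's exact adjusted p of 0.0785 without list 2. Gibberellin genes also missed the threshold against genes of matched length (adjusted permutation p = 0.126), as auxin biosynthesis did (0.0777), and both missed it with windows of 1 kb and 5 kb. With regions shifted together along the chromosomes the gibberellin list had an adjusted permutation p of 0.0979.

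Several groups did not pass the test in the main comparison. Chlorophyll biosynthesis had a region at 0 of 13 genes (exact interval 0 to 24.7%, Fisher's exact adjusted p = 0.336). Light-harvesting antenna genes had 2 of 19, LHCA2 and LHCB2.3, with list 3 folds of 5.99 and 3.68 (Fisher's exact adjusted p = 0.794). Clock genes had 3 of 16 (adjusted p = 0.794, Fisher's exact), GI, PRR9 and PRR5, with list 2 folds of 5.83, 3.97 and 2.41. The PIF family list had 3 of 8 members (Fisher's exact adjusted p = 0.176). These were PIF4, PIF6 with folds of 1.02, 10.4 and 18.2, and SPT with 1.66, 1.94 and 3.97, and PIF3, PIF5 and PIF7 were not among them. The family passed in the better-ranked 50% of each list (Fisher's exact adjusted p = 0.0394) and at the authors' false discovery rate of 1% (0.000142). Only 14 genes were assigned at that rate, PIF4 and PIF6 among them, and binding at PIF4 was not separated from DNA of the transgene. The pair of PIF4 and PIF1 as a list had 1 of 2 (Fisher's exact adjusted p = 0.348, and 0.00714 at that rate). B-box factors had 8 of 30 (Fisher's exact adjusted p = 0.18), among them BBX29 with list 3 fold 14.5, BBX28 with 11.1, BBX8 with 4.19 and BBX21 with 4.18. They passed in 4 of 15 alternatives: without list 1 (Fisher's exact adjusted p = 0.0363), in the better-ranked 50% (0.0428), within 1 kb (0.0322) and with the nearest gene alone (0.016). Wall-loosening genes had 12 of 57 (Fisher's exact adjusted p = 0.348), with list 3 folds of 10.2 at EXPA1, 5.86 at EXPA9, 3.74 at EXPA8 and 4.90 at XTH9, and passed with the nearest gene alone (Fisher's exact adjusted p = 0.0229).

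Of the control lists, ribosomal proteins had a region at 7 of 44 genes (15.9%, Fisher's exact adjusted p = 0.835) and core histones at 4 of 21 (19.0%, adjusted p = 0.64, Fisher's exact). RPL23A, RPL18, RPS5A and RPL12 had list 2 folds of 2.59, 1.99, 2.67 and 2.48. HTR12, HTA5, HTA10 and HTB1 had list 3 folds of 5.52, 5.70, 2.81 and 3.10. Actins and tubulins, chosen as a control, passed the threshold with 10 of 24 genes (41.7%, interval 22.1 to 63.4, Fisher's exact adjusted p = 0.00499). Their odds ratio of 3.98 was above those of the called photoreceptor (2.97), gibberellin (2.79) and SAUR (2.44) lists. It was near those of auxin biosynthesis (4.18) and ethylene (4.29). The exact intervals of shade targets, Aux/IAA, HD-Zip class II and brassinosteroid genes began at 50.9, 35.7, 39.99 and 34.9%, below the control's upper end of 63.4%. No called list was tested against this control, so no call was shown to exceed it. TUA6, TUB5, ACT7 and TUB6 had list 2 folds of 2.88, 2.58, 1.92 and 3.62, and ACT7 another list 2 peak of 3.12. Without list 2 and without list 3 the adjusted p of actins and tubulins was 0.0785 and 0.1 (Fisher's exact), and with regions that needed a list 1 peak it was 0.132. With a window of 5 kb it was 0.0563.

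Outside the lists, the highest median folds among regions in all 3 lists stood beside several genes without a symbol. AT3G21320 had folds of 1.12, 11.35 and 16.8 at 7503002 to 7504297 on chromosome 3. AT5G02580 had 1.03, 10.6 and 19.25, AT5G57670 had 1.18, 9.74 and 13.8, AT1G21050 had 1.07, 9.52 and 15.8, and AT3G44610 had 0.67, 9.52 and 15.6, with another list 1 peak of 1.32 in the gene. AT4G30410 had its summit in the gene, with folds of 2.09, 8.94 and 13.2. HB53 (AT5G66700), a homeobox gene, had 2.02, 11.03 and 16.0 at 26632017 to 26633210 on chromosome 5. ASY3, AT5G54480 and AT2G18780 were assigned the regions also assigned to PIL1, BBX29 and PHYB. The summit lay nearer to ASY3 than to PIL1, but nearer to BBX29 and PHYB than to AT5G54480 and AT2G18780.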

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

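The tests in this part were chosen after the patterns had been seen, except 2 for actins and tubulins: the test of the nearest gene was written down before its result, and the comparison with genes of matched length was fixed before the data were examined, though its use as a test here was written after.

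The tag column held a signal in list 1: 100% of its counts were multiples of 5, from 65 upward, against 20.5% and 20.8% in lists 2 and 3. The limit of 3 tags per position named in the header would let counts take every remainder, which 12177 peaks did not do. Each read copied 5 times before that limit would leave multiples of 3, which 24.0% of the counts were. Counts multiplied by 5 after the duplicate limit stay open: 0 counts left a remainder, which is the pattern itself, and the header's total of 12766185 tags also divides by 5, which multiplied peak counts alone would not need but 1 total in 5 does by chance. The header of list 1 gives more tags after filtering than before, so its other values, the limit among them, are uncertain too, and no biological explanation was tested.

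Lists 2 and 3 shared the exact start in 1240 of 2454 overlapping pairs, while nearly equal edges of strong sites in separate libraries would spread the starts over neighbouring bases, and no other distance within 20 bp held more than 15 pairs. A common control would act on lists 1 and 2, whose headers name the same one, and these shared a start in 3.28% of pairs against 50.5%, although their 53 pairs stand out against at most 6 at any other distance within 20 bp. In the 621 peaks with both edges the same, the tag ratio of the lists varied by 0.234 of the variance from counting error, where separate libraries at any steady ratio would give 0.892 or more (lower end of the 95% range). List 2 had fewer tags than list 3 in 0 of these peaks, and counting error around their own ratio would give 33.7. This is consistent with reads shared by the libraries behind lists 2 and 3, but the header totals put list 2 lower, and reads were not used here; no biological explanation was tested.

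Actins and tubulins were fixed as a control list and still had a shared region at 10 of 24 genes. Summits that lie nearer to a neighbouring gene do not account for it, since the actin or tubulin gene was the nearest one for 11 of 12 regions (91.7%). The nearest gene need not be the one a summit belongs to, which this test cannot decide. Gene length does not account for all of it, with an adjusted permutation p of 0.021 against genes of matched length. Signal that gathers equally at the ends of all highly active genes would give the 3 control lists equal shares, and with 7 of 44 ribosomal protein genes, organellar ones among them, and 4 of 21 histone genes the exact p over the lists was 0.0502. Actins and tubulins against both others gave a Fisher's exact p of 0.0234, but that comparison picks the list for its value, and gene activity was not measured here. Signal that gathers at the ends of highly active genes stays open. So do summits that belong to a gene other than the nearest and binding of PIF4 at these genes, which were not tested.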

How the results depend on the processing

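Sharing beyond random placement (3153 regions) held under every setting of peaks, overlap and left-out list and against placements within 50 kb, but the counts moved. At the authors' false discovery rate of 1%, 11 regions were shared, 0 were in all 3 lists, and 14 genes were assigned. List 3 had only 2 peaks at that rate, so the 0 says little about agreement between the 3 lists. The 3 gene lists that passed there were shade targets, the only 1 of the 10 called lists kept, the PIF family (Fisher's exact adjusted p = 0.000142) and the pair of PIF4 and PIF1 (0.00714). The PIF family and the pair both count PIF4 itself, where transgene DNA was not separated from binding. In the better-ranked 50% of each list there were 1525 shared regions, 260 in all 3 lists and 2023 genes, and the fold correlations of list 1 with lists 2 and 3 were 0.0674 and 0.0821 (permutation p = 0.127 and 0.176). Regions in all 3 lists numbered 218 with equal numbers of peaks, 128 with reciprocal overlap and 369 with summits within 100 bp. Windows of 5 kb gave 7405 genes and 6 lists past the threshold, and the nearest gene alone 2738 genes and 13 lists, with B-box factors, auxin response factors and wall loosening added. Leaving out each list in turn gave 852 to 2412 regions shared by both others, which also stand in for regions in all lists, 1319 to 3208 genes, and 3 to 11 gene lists. The 3 lists past the threshold without list 2 were shade targets, photoreceptors and HD-Zip class II, and without list 3 shade targets, photoreceptors and ethylene.

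Chosen after seeing the data, regions that needed a list 1 peak numbered 1527, with 2278 genes and 2 lists past the threshold, shade targets and HD-Zip class II. The genes of these regions were assigned from the summit of the highest-fold peak, which need not be the list 1 peak. Regions of lists 2 and 3 without a list 1 peak gave 2146 genes and 9 lists. Shade targets passed in all 15 alternatives (adjusted p from 7.14e-11 to 0.00699). The share of summits outside genes stayed above random in all 10 alternatives run, from 60.2% to 81.8%. The causes were not tested where none is given. The upstream share, the motif shares and their alternatives were not run, since strand and sequence were not used here. No paired analysis was possible because each list already sets a ChIP against a control and gives no values per wild-type library.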

Other observations

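Beyond the fixed lists, families of at least 10 genes that share a symbol stem were tested in the same way, a choice made after seeing the data. The stems MEE, ATL and EMB, the last in capitals and in small letters, were left out. Of 133 families, 6 passed a Benjamini-Hochberg adjusted p of 0.05 in Fisher's exact test. Among them were the IAA stem, with a region at 13 of 24 genes, and the SAUR stem, with 8 of 16. Both overlap the Aux/IAA and SAUR lists described above, which hold 29 and 79 genes, but are smaller sets with other odds ratios. Of these 6, 3 passed without list 1 (IAA, RAD and WNK), 0 without list 2 and 0 without list 3, where 5 and 12 of the 133 had an unadjusted Fisher's exact p under 0.05. Odds ratios of WNK, RAD, GRF, SAUR, NAC and IAA without list 2 were 13.2, 8.83, 3.31, 2.83, 1.93 and 1.80. With all lists these odds ratios were 13.0, 8.92, 4.18, 5.57, 2.74 and 6.59. With regions that needed a list 1 peak 1 of the 6 passed, NAC (Fisher's exact adjusted p = 0.045). WNK kinases had a shared region at 7 of 10 genes (70.0%, exact interval 34.8 to 93.3, Fisher's exact adjusted p = 0.00598). WNK3 had the highest folds of these, 7.01 in list 2 and 11.4 in list 3, and WNK1, WNK4 and WNK10 had a region in all 3 lists. NAC transcription factors had 26 of 79 (32.9%, interval 22.7 to 44.4, Fisher's exact adjusted p = 0.00598). NAC075 and NAC089 had list 3 folds of 6.09 and 6.17, while neighbouring pairs such as NAC004 and NAC005 shared a region. The RAD stem had 8 of 13 genes (Fisher's exact adjusted p = 0.00598), with RAD50 at folds of 5.40 and 11 in lists 2 and 3. The GRF stem, which joins growth-regulating factors and 14-3-3 proteins, had 9 of 21 (Fisher's exact adjusted p = 0.0497, and 0.0512 with no stem left out). With all regions shifted together along the chromosomes, 1.59 WNK, 10.8 NAC, 2.27 RAD and 3.06 GRF genes had a region on average.

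MicroRNA genes had a shared region at 37 of 326 (11.3%), against 15.2% of protein-coding genes (Fisher's exact test, two-sided, p = 0.0523). Gene length was not matched in this comparison, and a shorter gene offers a narrower window for a summit. Members with a region included MIR156c, MIR157a, MIR159a, MIR166a, MIR167a and MIR396a.

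Some header values depended on one another. For list 2 the 8634942 tags left after filtering equal the total of 9385807 less a redundancy of 0.08, the rounded rate in the header, to the last whole tag. For list 1 the same product is 11234243, which makes up the leading digits of the 112342435 tags in its header. For list 3 the product is 10694371, and the header gives 10730507.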
